A study of Homo sapiens with 6 samples.

How the data were processed

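The series holds 6 RNA-seq libraries of U251 glioma cells, 3 controls and 3 treated with 6-shogaol for 24 h. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum, total RNA was extracted with Trizol, and libraries were made with a SMARTER mRNA-Seq kit. Groups and replicate numbers were taken from the sample titles. The aligner, the counting tool and the strand setting were not given in the sources used here. Per the submitters' processing notes, the genome builds were the mouse builds GRCm38 and mm10. The deposited tables do not carry mouse genes: all 60612 identifiers are human Ensembl identifiers and 0 are mouse ones. Of these, 58394 are also in GENCODE release 29 on the human build GRCh38, where 72.7% have the same chromosome, start and end and 99.98% overlap the same gene. Coordinates are printed as the deposited table gives them.

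The authors deposited a table of raw counts per gene, not normalized, with 1 column per library. They also deposited FPKM values, per the file headers, for the same genes, with a copy of the counts in which 0 values differed from the count table. Among the FPKM values, 0.0001 stands in for most values with a count of 0, and 110 values lie below it. That table also pairs each identifier with a gene symbol and with Gene Ontology and KEGG terms. It held 0 columns of samples outside the series.

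Genes were tested in R 4.3.3 with edgeR 4.0.16 on the deposited counts. Low genes were removed with filterByExpr, which left 19279 genes, and 12752 further genes with counts were not tested. Libraries were scaled by TMM and the group effect was tested with glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled. The common biological coefficient of variation was 25.3%. Totals ran from 43516840 to 60018999 counts per library, so that a gene at 0 could have had up to 0.05 to 0.0689 CPM (3 counts, covering counting error only). Between 23949 and 25007 genes had at least 1 count in a library.

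Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 3 tested members were tested with camera on voom values (limma 3.58.1), with a preset inter-gene correlation of 0.01 and again with an estimated one, and with fry, adjusting over all lists. Term enrichment used a hypergeometric test against tested genes with at least 1 term, for terms of 10 to 500 genes. Shares were compared by two-sided exact permutation tests, which cannot give a p below 0.1 with 3 libraries against 3. The rule named the 6 largest rises and the 6 largest falls among called genes with a symbol, a mean of at least 5 CPM and no overlap of the groups. It further named the 2 members of each list with the largest change at that level, with the largest in the other direction where members went both ways, and the 2 genes with the smallest adjusted p per direction. It named 42 genes, of which 1 is not reported here. Exon overlap with neighbouring genes came from GENCODE 29, counting neighbours with a mean of at least 10 counts.

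The libraries were compared before averaging. Log2 CPM correlated across genes between all pairs of libraries (Pearson's r from 0.962 to 0.973), and genes are not independent replicates. Replicates differed by far more than sampling noise (chi-square per degree of freedom from 34.4 to 70.8), so no library was a copy of another. Principal component 1 held 28.0% of the variance and had the controls on 1 side and the treated libraries on the other. On component 2 (20.6%), 6-shogaol replicate 1 lay at -61.8 and the other libraries between -22.6 and 33.9.

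The scripts were tested on simulated counts with the means, dispersions and library sizes of this comparison over 19279 genes. At each size 50 genes above a minimum mean count were changed. The edgeR step recovered 16% at 1.5-fold, 60% at 2-fold, 90% at 3-fold and 86% at 4-fold, with 10 false calls (7.35% of calls). With 1 list shifted 2-fold, camera called that list and 0 of the others, and fry called 1 of the others. Simulated genes were drawn independently of each other, so this could not show false calls of lists whose members are correlated. The limma step on simulated FPKM recovered 120 of 178 changed genes among 12508, with 7 false calls.

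Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 3 libraries, or with no filter. Robust moderation, counts thinned to the smallest total and a fit without mitochondrially encoded genes were added after the data were seen. A planned comparison with fold changes from the authors was not made, since the tables used here hold none.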

Results

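RNA sequencing measured the transcriptome of U251 cells, an established human glioma line of astrocytic origin, after 24 h with or without 6-shogaol. 6-shogaol is a pungent constituent of dried ginger, an unsaturated ketone that reacts readily with thiol groups. The labels give its dose as 60 and write the unit as "μm", read here as micromolar. The study had 2 groups of 3 libraries, and the comparison asked which transcripts differ between treated and control glioma cells in a search for anti-cancer effects of the compound. Control libraries 1, 2 and 3 held 52132767, 58998660 and 60018999 counts. The 6-shogaol libraries 1, 2 and 3 held 55225898, 50622607 and 43516840 counts. Nothing in the labels states that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

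Among fixed gene lists, ATF4 targets, immediate early genes and DNA replication genes were called higher with 6-shogaol and interferon-stimulated and mitotic genes lower by camera with its preset correlation. With an estimated correlation the calls of ATF4 targets, DNA replication genes and interferon-stimulated genes were lost (adjusted p = 0.065, 0.065 and 0.091). The estimates for these lists were 0.16, 0.08 and 0.50. Glycolysis and hypoxia targets, with an estimate of -0.005, also lost their call (camera adjusted p = 0.065), so a loss need not reflect correlated members. Of 19279 genes tested, 322 were higher and 329 lower with 6-shogaol in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were seen in 45 higher and 60 lower genes. Among the called genes, 8 had no counts in any library of 1 group, so their fitted fold changes have no meaning as sizes.

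The largest rise among genes with a mean of at least 5 CPM was that of HSPA6, a stress-inducible member of the HSP70 chaperone family (ENSG00000173110, chromosome 1, 161524540 to 161526894 in GRCh38). Its level went from 0.453 ± 0.145 CPM in controls to 35.8 ± 5.39 CPM with 6-shogaol (mean ± SD, n = 3), a log2 fold change of 6.29 (SE 0.25, edgeR adjusted p = 0.000285). The controls held 16, 35 and 27 HSPA6 counts and the treated libraries 2369, 1680 and 1390. GDF15, a secreted stress cytokine of the TGF-beta superfamily (chromosome 19, 18374731 to 18389176), rose from 56.0 ± 0.713 to 210 ± 14.7 CPM (log2 fold change 1.90, SE 0.07, edgeR adjusted p = 0.000285). TFRC, the transferrin receptor that takes up iron (chromosome 3, 196027183 to 196082096), rose from 306 ± 81.4 to 1018 ± 29.3 CPM (log2 fold change 1.74). UNC5B, a netrin receptor, rose by 1.52 on the log2 scale, and TRIB3, a pseudokinase induced by stress, by 1.39. ENTPD1-AS1 rose by 1.67, although it lies antisense to ENTPD1 and shares 3.6% of its exon length with it, and the strand used in counting was not stated. Among called genes at that level SCUBE3 fell the most (log2 fold change -2.08, SE 0.28, edgeR adjusted p = 0.0159), from 21.3 ± 0.255 to 5.01 ± 2.02 CPM. TACR1, the receptor of substance P, had a log2 fold change of -1.74. The processed pseudogene TCEA1P2, whose reads may belong to its parent gene, had a value of -1.78. SCUBE3 lost its call without control replicate 1, 2 or 3 or 6-shogaol replicate 2, ENTPD1-AS1 without control replicate 3 or 6-shogaol replicate 2, and TCEA1P2 without 6-shogaol replicate 2. MAVS, the mitochondrial adaptor of cytoplasmic RNA sensing (chromosome 20, 3846799 to 3876123), fell from 256 ± 10.5 to 125 ± 5.65 CPM (log2 fold change -1.03, edgeR adjusted p = 0.00209).

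**Figure D1:**
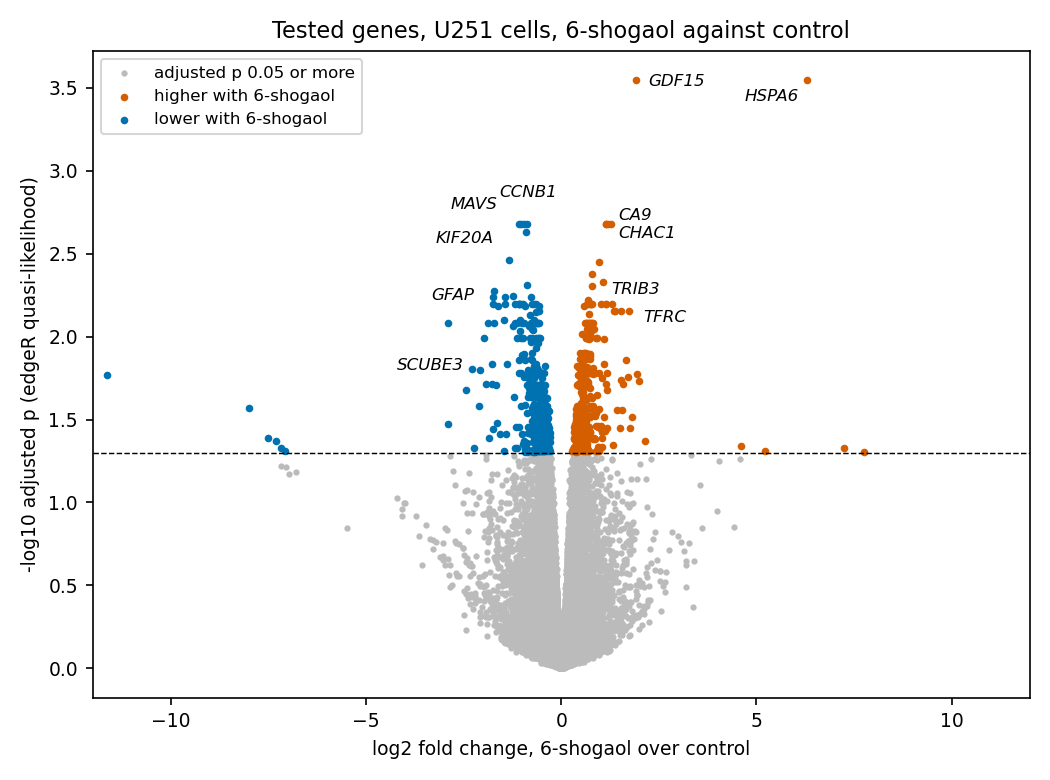
Log2 fold change of 6-shogaol over control (horizontal axis) against -log10 of the edgeR adjusted p (vertical axis) for the 19279 tested genes; orange points are the 322 higher and blue points the 329 lower genes, and the dashed line marks an adjusted p of 0.05. HSPA6 lies at 6.29, and the other 10 called genes beyond 4 in either direction were all below the mean of 5 CPM required of named genes.

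**Figure D2:**
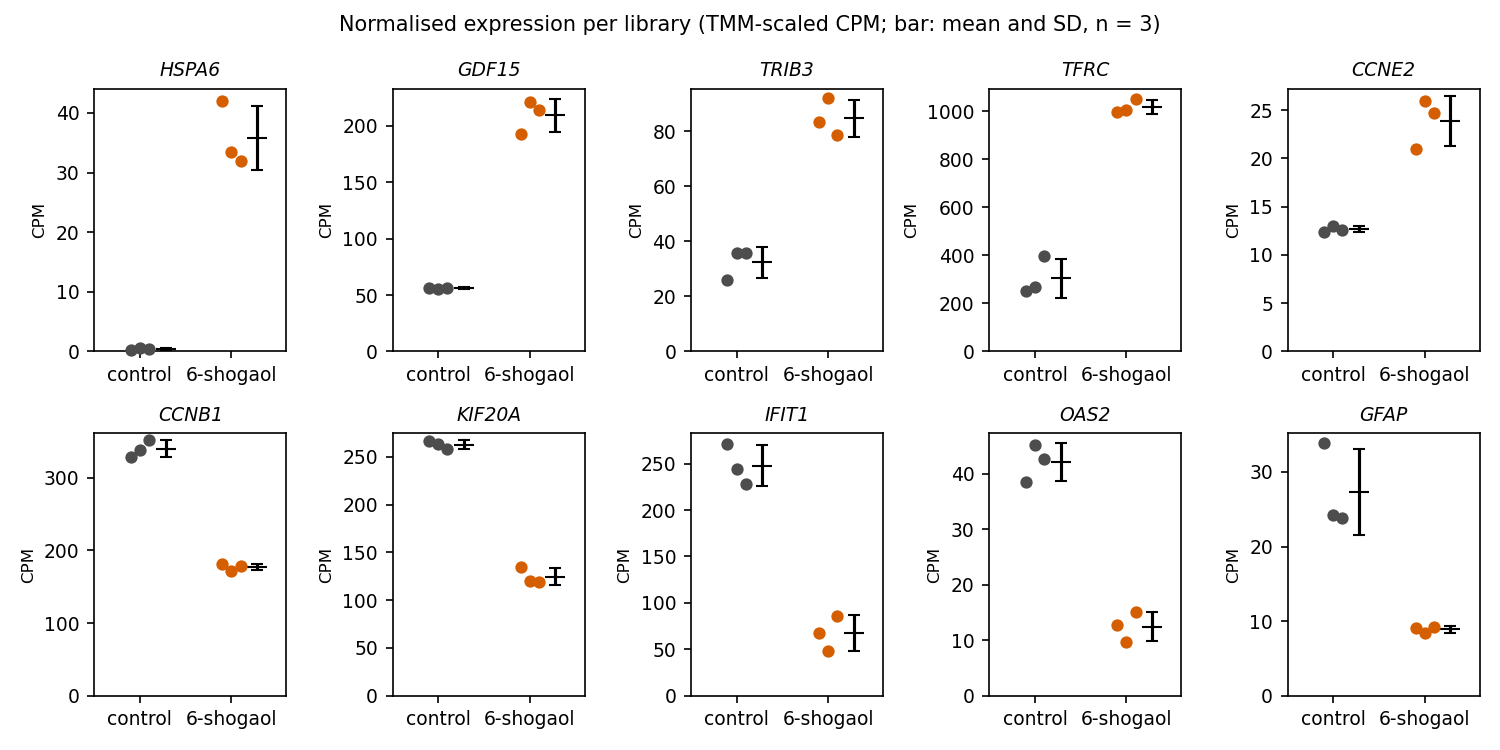
TMM-scaled CPM (vertical axes, each from 0) of 10 named genes in the 3 control and the 3 6-shogaol libraries; points are libraries, and the bars beside them show the mean and SD. HSPA6 rose from 0.453 to 35.8 CPM and IFIT1 fell from 248 to 67.4 CPM, and the groups do not overlap in any of the 10 panels.

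Targets of the transcription factor ATF4 in the integrated stress response rose as a group. Of 22 tested members 13 rose (18 adjusted over the list alone), among them GDF15, TRIB3 and CHAC1, which degrades glutathione (log2 fold change 1.14). The median log2 fold change of the list was 0.67 (camera adjusted p = 8.87e-19, adjusted p = 0.065 with an estimated correlation), and 7 members were called without control replicate 2. The ATF4 transcript itself, chosen after its values were seen, stood at 42.1, 38.7 and 86.5 CPM in control replicates 1, 2 and 3 and at 52.3, 59.7 and 58.5 CPM with 6-shogaol, and did not pass (edgeR adjusted p = 0.974), control replicate 3 alone lying above the treated libraries. Of 20 endoplasmic reticulum chaperone and degradation genes 3 rose (8 adjusted over the list alone). CANX, encoding the lectin chaperone calnexin, had a value of 0.42 and EDEM1, which directs misfolded glycoproteins to degradation, of 0.41, with 9.7% of the EDEM1 exon length shared with another gene. The list had a median of 0.19 (camera adjusted p = 4.69e-05, adjusted p = 0.091 with an estimated correlation). Its called members numbered 5 without 6-shogaol replicate 1 and at most 1 when any other library was left out. Of 27 targets of the oxidative stress factor NRF2 3 rose (adjusted over the list alone, 9 rose and 1 fell). The cystine transporter SLC7A11 had a value of 0.47 and the efflux pump ABCC3 of 0.45, and the list median was 0.21 (camera adjusted p = 0.000471, adjusted p = 0.18 with an estimated correlation). At most 1 NRF2 target was called when any library other than 6-shogaol replicate 1 was left out. HMOX1 and NQO1, usual markers of NRF2 activity chosen after their values were seen, had log2 fold changes of 0.37 and 0.14 and did not pass (edgeR adjusted p = 0.063 and 0.269).

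Heat shock genes other than HSPA6 did not rise as a group. Of 20 tested members 3 fell (adjusted over the list alone, 2 rose and 7 fell). DNAJA1, an HSP40 co-chaperone, had a log2 fold change of -0.59 and the small heat shock protein gene HSPB1 of -0.56. The list had a median of -0.14 (camera adjusted p = 0.00513, adjusted p = 0.091 with an estimated correlation). Its mean was -0.08, but 0.04 with the replicate block and 0.11 without control replicate 2. Per library the mean log2 CPM of the list, minus the control mean, was -0.09, 0.17 and -0.07 in control replicates 1, 2 and 3. With 6-shogaol it was 0.04, 0.01 and 0.03, within the range of the controls. HSPA1A and HSPA1B are near-identical copies whose counts were divided unevenly, HSPA1A taking 1.65%, 32.6% and 0.865% of the pair in the controls and 34.6%, 28.6% and 33.6% in the treated libraries. Their sum was 180 ± 41.1 CPM in controls and 222 ± 23.3 CPM with 6-shogaol (two-sided exact permutation test, p = 0.3, where the smallest possible is 0.1, so that the test could not pass 0.05). Of 17 ferroptosis regulators 3 rose, TFRC, CHAC1 and SLC7A11, and GPX4, a lipid peroxide reductase, fell (log2 fold change -0.36). SLC7A11 and GPX4 each lost the call in 5 of the 6 fits without 1 library, GPX4 in all but the fit without 6-shogaol replicate 1. CHAC1 was also counted among ATF4 targets and SLC7A11 among NRF2 targets, so these lists are not independent. The list mixes genes of opposing roles, so its median gives no direction of ferroptosis. Adjusted over the list alone 8 rose and 2 fell, and the list median was 0.19 (camera adjusted p = 0.00358, adjusted p = 0.091 with an estimated correlation). Of 23 autophagy and lysosome genes 1 rose (2 adjusted over the list alone), the cholesterol transporter NPC1 at 0.41, which did not pass in counts thinned to the smallest total or when any library other than 6-shogaol replicate 1 was left out. That list had a median of 0.10 (camera adjusted p = 0.0184, adjusted p = 0.10 with an estimated correlation), and without 6-shogaol replicate 2 it was not called (median 0.05, adjusted p = 0.0679), while without control replicate 2 its median was 0.16. For the 3 tested metallothioneins edgeR called 0 over all genes and 3 lower adjusted over the list alone, against 3 lower at unadjusted p under 0.05, 3 lower in DESeq2 and 0 in limma on FPKM. Their median was -0.40 (camera adjusted p = 0.00358, adjusted p = 0.091 with an estimated correlation). Of 31 proteasome subunits edgeR called 0, over all genes and adjusted over the list alone, with 2 higher and 1 lower at unadjusted p under 0.05, 1 lower in DESeq2 and 0 in limma, and the list was not called (camera adjusted p = 0.447).

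Of 26 DNA replication and S-phase genes 11 rose (adjusted over the list alone, 16 rose and 1 fell). RRM2, the ribonucleotide reductase subunit that supplies deoxynucleotides (chromosome 2, 10120698 to 10210597), rose from 135 ± 6.37 to 229 ± 13.7 CPM (log2 fold change 0.76, SE 0.07, edgeR adjusted p = 0.00635). CCNE2, a cyclin of S-phase entry, had a value of 0.92 but shares 37.1% of its exon length with neighbouring genes that include INTS8, and it lost its call without control replicate 1, 2 or 3. The median of the list was 0.36 (camera adjusted p = 4.21e-11, adjusted p = 0.065 with an estimated correlation). Without control replicates 1, 2 and 3 the called S-phase genes numbered 2, 1 and 2, and without 6-shogaol replicates 1, 2 and 3 they numbered 10, 3 and 3. Of 23 mitotic genes 8 fell (14 adjusted over the list alone), against 4, 4 and 5 without control replicates 1, 2 and 3 and 8, 4 and 4 without 6-shogaol replicates 1, 2 and 3. CCNB1, the mitotic cyclin (chromosome 5, 69167135 to 69178245), fell from 340 ± 11.7 to 177 ± 4.61 CPM (log2 fold change -0.94, SE 0.06, edgeR adjusted p = 0.00209). KIF20A, a kinesin of cytokinesis, fell from 263 ± 4.35 to 125 ± 8.72 CPM (log2 fold change -1.08). The list had a median of -0.28 and was called under either correlation with all 6 libraries (camera adjusted p = 6.44e-10, adjusted p = 0.039 with an estimated correlation). The call with an estimated correlation was lost in every fit without 1 library (adjusted p from 0.0624 to 0.148). It was also lost with the filter of 1 CPM (0.0524) and with the replicate block (0.209). Fits without 1 library or with the block leave fewer degrees of freedom. ATF4 targets, DNA replication genes and interferon-stimulated genes also had 0.209 with the block, so that loss does not single out mitotic genes. Of 11 tubulins 2 fell, TUBB4B (-0.42) and TUBA1C (-0.40), the latter sharing 25.0% of its exon length with genes that include TUBA1A. The count of 2 was the same without control replicate 3, was 4 without 6-shogaol replicate 1, and no tubulin was called when any other library was left out. Adjusted over the list alone 1 tubulin rose and 4 fell, and the list median was -0.21 (camera adjusted p = 0.019, adjusted p = 0.29 with an estimated correlation). Without 6-shogaol replicate 3 the tubulins were not called (adjusted p = 0.0602), and without 6-shogaol replicate 1 their median was -0.37.

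Genes of cell death and p53 showed few called changes in edgeR adjusted over all genes. Of 21 p53 targets 1 fell, the quinone oxidoreductase gene TP53I3 (log2 fold change -0.88, not called when any library other than 6-shogaol replicate 1 was left out), and adjusted over the list alone 5 rose and 1 fell. At unadjusted p under 0.05 there were 5 higher and 2 lower, DESeq2 called 3 higher and 1 lower, and limma called 1 lower. The list was not called (median 0.06, camera adjusted p = 0.315). CDKN1A, the p21 gene chosen after its value was seen, went from 135 ± 40.4 to 253 ± 5.01 CPM. It did not pass (log2 fold change 0.91, edgeR adjusted p = 0.0689), although its groups did not overlap. Of 21 BCL2 family and death receptor genes edgeR called 0, over all genes and adjusted over the list alone. At unadjusted p under 0.05 there were 4 higher and 4 lower, DESeq2 called 2 higher and 2 lower, and limma called 0. That list's median was -0.02, its mean 0.05 and camera's direction upward (adjusted p = 0.989). Camera tests for a shared direction, so it could not show members that moved both ways. Fry's test without regard to direction passed for this list and for p53 targets (fry adjusted p = 0.00326 and 0.000596). That test passed for most of the lists, proteasome subunits among them (fry adjusted p = 0.014), so it does not single these out.

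Interferon-stimulated genes fell with 6-shogaol. Of 22 tested members 19 fell (20 adjusted over the list alone), with a median log2 fold change of -1.18 (camera adjusted p = 8.28e-23, adjusted p = 0.091 with an estimated correlation). IFIT1, an RNA-binding antiviral effector (chromosome 10, 89392546 to 89406487), fell from 248 ± 22.3 to 67.4 ± 19.1 CPM (log2 fold change -1.88, SE 0.20, edgeR adjusted p = 0.00828). OAS2, a sensor of double-stranded RNA (chromosome 12, 112978395 to 113011723), fell from 42.1 ± 3.41 to 12.5 ± 2.68 CPM (log2 fold change -1.76). MX2, an antiviral GTPase outside the list, had a value of -1.85 (edgeR adjusted p = 0.0411) and did not pass with robust moderation, with no filter, with the replicate block, in limma on FPKM with no filter, or without control replicate 1, 2 or 3 or 6-shogaol replicate 1. The list members IRF9, IRF7 and XAF1 did not pass. Without control replicates 1, 2 and 3 the called members numbered 12, 11 and 11, and without 6-shogaol replicates 1, 2 and 3 they numbered 16, 14 and 16.

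**Figure D3:**
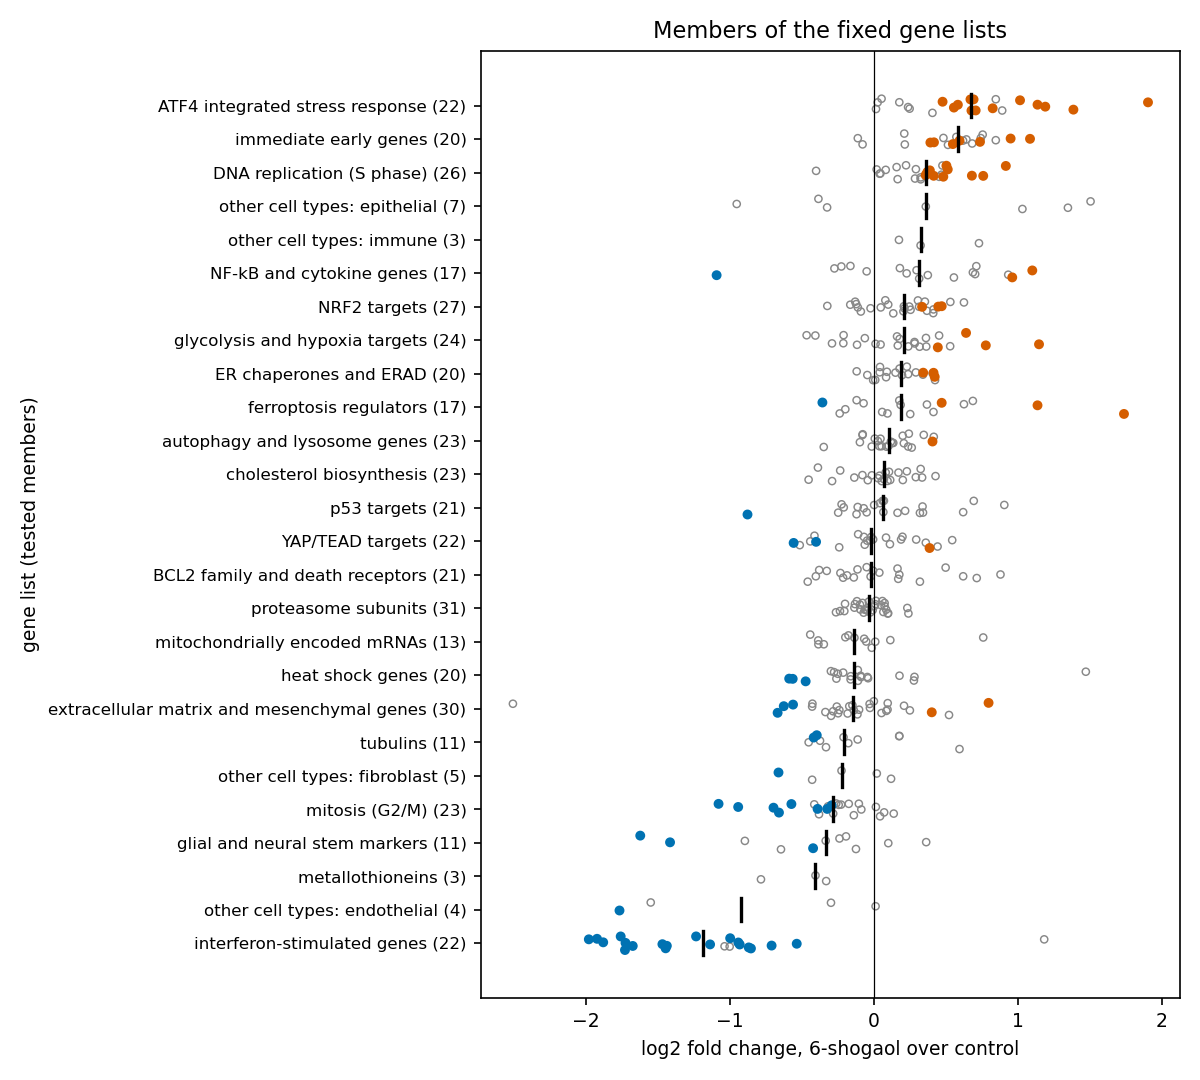
Log2 fold change of 6-shogaol over control (horizontal axis) for each tested member of the 26 gene lists (vertical axis, number of tested members in parentheses); filled points passed the edgeR test over all genes, orange higher and blue lower, open points did not, and black bars are list medians. The medians run from -1.18 for interferon-stimulated genes to 0.67 for ATF4 targets.

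Immediate early genes rose with 6-shogaol. Of 20 tested members 7 rose (11 adjusted over the list alone), including DUSP5, a phosphatase of ERK (log2 fold change 1.08), and IER3 (0.74). DUSP5 lost its call without control replicate 1 or 2 or 6-shogaol replicate 2 or 3, and IER3 without control replicate 1. The list median was 0.58, and the list was called under either correlation with all 6 libraries (camera adjusted p = 1.97e-08, adjusted p = 0.039 with an estimated correlation). The call with an estimated correlation was lost in every fit without 1 library (adjusted p from 0.0662 to 0.148). It was also lost with the filter of 1 CPM (0.0524) and with the replicate block (0.209). As for mitotic genes, fits without 1 library or with the block leave fewer degrees of freedom, and the loss with the block does not single out this list. At most 2 immediate early genes were called when any library other than 6-shogaol replicate 1 was left out. Of 17 NF-kB and cytokine genes 2 rose and 1 fell. The neutrophil chemokine CXCL8 had a log2 fold change of 1.10 and the monocyte chemokine CCL2 of -1.09, a call that CCL2 lost in every fit without 1 library and CXCL8 without control replicate 2 or 3. Adjusted over the list alone 6 rose and 1 fell, with a list median of 0.32 (camera adjusted p = 0.00971, adjusted p = 0.091 with an estimated correlation). At most 1 of these genes was called when any library other than 6-shogaol replicate 1 was left out. Of 24 glycolysis and hypoxia targets 4 rose (adjusted over the list alone, 11 rose and 2 fell). NDRG1, a hypoxia-inducible gene, had a value of 0.78, and CA9, carbonic anhydrase 9, of 1.15, with 38.5% of the CA9 exon length shared with ARHGEF39. The list median was 0.21 (camera adjusted p = 0.000371, adjusted p = 0.065 with an estimated correlation). Without 6-shogaol replicate 1 the called targets numbered 8 higher and 1 lower, and 2 were higher without control replicate 1, 6-shogaol replicate 2 or 6-shogaol replicate 3. Of 23 cholesterol biosynthesis genes edgeR called 0, over all genes and adjusted over the list alone. At unadjusted p under 0.05 there were 2 higher and 3 lower, DESeq2 called 1 higher and 1 lower, limma called 1 higher, and the list was not called (camera adjusted p = 0.479).

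Of 11 glial and neural stem markers 3 fell (5 adjusted over the list alone). GFAP, the astrocyte intermediate filament (chromosome 17, 44903159 to 44916937), fell from 27.3 ± 5.73 to 8.88 ± 0.424 CPM (log2 fold change -1.62, SE 0.16, edgeR adjusted p = 0.00655), with 18.4% of its exon length shared with CCDC103 and FAM187A. NES, encoding nestin, had a value of -0.42 (edgeR adjusted p = 0.0484) and did not pass in limma on FPKM. The list median was -0.33 (camera adjusted p = 0.00109, adjusted p = 0.14 with an estimated correlation), and -0.22 without control replicate 2. A single marker was called when any library other than 6-shogaol replicate 1 was left out. Of 30 extracellular matrix and mesenchymal genes 2 rose and 3 fell (adjusted over the list alone, 5 rose and 9 fell). COL1A1, a fibrillar collagen chain, had a value of -0.67. The list median was -0.14 (camera adjusted p = 0.0414, adjusted p = 0.42 with an estimated correlation), and the list was not called without control replicate 3 (adjusted p = 0.134) or 6-shogaol replicate 2 (adjusted p = 0.117). Fry did not call this list (adjusted p = 0.222). At most 1 matrix gene was higher and 1 lower when any library other than 6-shogaol replicate 1 was left out. Of 22 YAP/TEAD targets 1 rose, DOCK5 (0.39), and 2 fell, ANKRD1 (-0.56) and TGFB2 (-0.40, with 26.6% of its exon length shared with TGFB2-OT1). Adjusted over the list alone 6 rose and 4 fell, and the list was not called (median -0.02, mean -0.01, camera's direction upward, adjusted p = 0.779). ANKRD1 lost its call in every fit without 1 library, and DOCK5 and TGFB2 lost theirs in every such fit but the one without 6-shogaol replicate 1, in which 4 targets were lower.

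Markers of other cell types were measured beside these groups. Of 4 endothelial markers 1 fell, over all genes and adjusted over the list alone, and the highest mean among the 4 was 3.91 CPM in controls. The list median was -0.92 (camera adjusted p = 0.0434, adjusted p = 0.19 with an estimated correlation), and the call ended without control replicate 2 (adjusted p = 0.0709) or 6-shogaol replicate 2 (adjusted p = 0.0533), with the filter of 1 CPM (median -0.30, adjusted p = 0.111) and with the replicate block (adjusted p = 0.0729). Its median was -1.62 without control replicate 1, -1.78 without 6-shogaol replicate 1 and -1.60 without 6-shogaol replicate 3, fits in which 5 markers were tested. Only CDH5, chosen after its value was seen, passed, at 2.35 ± 0.14 CPM in controls and 0.691 ± 0.145 CPM with 6-shogaol. Of 5 fibroblast markers 1 fell, COL1A1, also when adjusted over the list alone, and COL1A1 lost its call when any library other than 6-shogaol replicate 1 was left out. The fibroblast list was not called (median -0.22, camera adjusted p = 0.35), and its median was 0.03 without control replicate 1 and 0.02 with the replicate block. For 3 immune markers edgeR called 0 over all genes and 1 higher adjusted over the list alone, against 1 higher at unadjusted p under 0.05, 1 higher in DESeq2 and 0 in limma. The immune median was 0.32, and the list was not called by camera (adjusted p = 0.158) but was called higher by fry (adjusted p = 0.045), a call lost without control replicate 2 (adjusted p = 0.121) or 3 (0.142), without 6-shogaol replicate 2 (0.125) or 3 (0.104) and with the replicate block (0.186). For 7 epithelial markers edgeR called 0 over all genes and 1 higher and 2 lower adjusted over the list alone. At unadjusted p under 0.05 there were 1 higher and 3 lower, and DESeq2 and limma each called 1 lower. The epithelial median was 0.36 and the mean 0.37 while camera's direction was downward (adjusted p = 0.711). That median ran from 0.12 without 6-shogaol replicate 3 to 0.71 without control replicate 3, and it was -0.36 with the filter of 1 CPM and -0.32 in thinned counts, where 4 and 5 markers were tested.

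Mitochondrially encoded genes took 10.4 ± 0.483% of counts in controls and 9.54 ± 1.10% with 6-shogaol (two-sided exact permutation test, p = 0.3, where the smallest possible is 0.1). Of 13 mitochondrially encoded mRNAs edgeR called 0 over all genes and 3 lower adjusted over the list alone, against 4 lower at unadjusted p under 0.05, 4 lower in DESeq2 and 0 in limma. The list median was -0.13 (camera adjusted p = 0.0414, adjusted p = 0.49 with an estimated correlation), and the call ended without 6-shogaol replicate 1 (median 0.0007, adjusted p = 0.738), without control replicate 1 (median -0.07, adjusted p = 0.0865) and without control replicate 2 (median -0.10, adjusted p = 0.0889). It also ended with the filter of 1 CPM (adjusted p = 0.0597) and by fry (adjusted p = 0.296), and without 6-shogaol replicate 2 the median was -0.24.

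**Figure D4:**
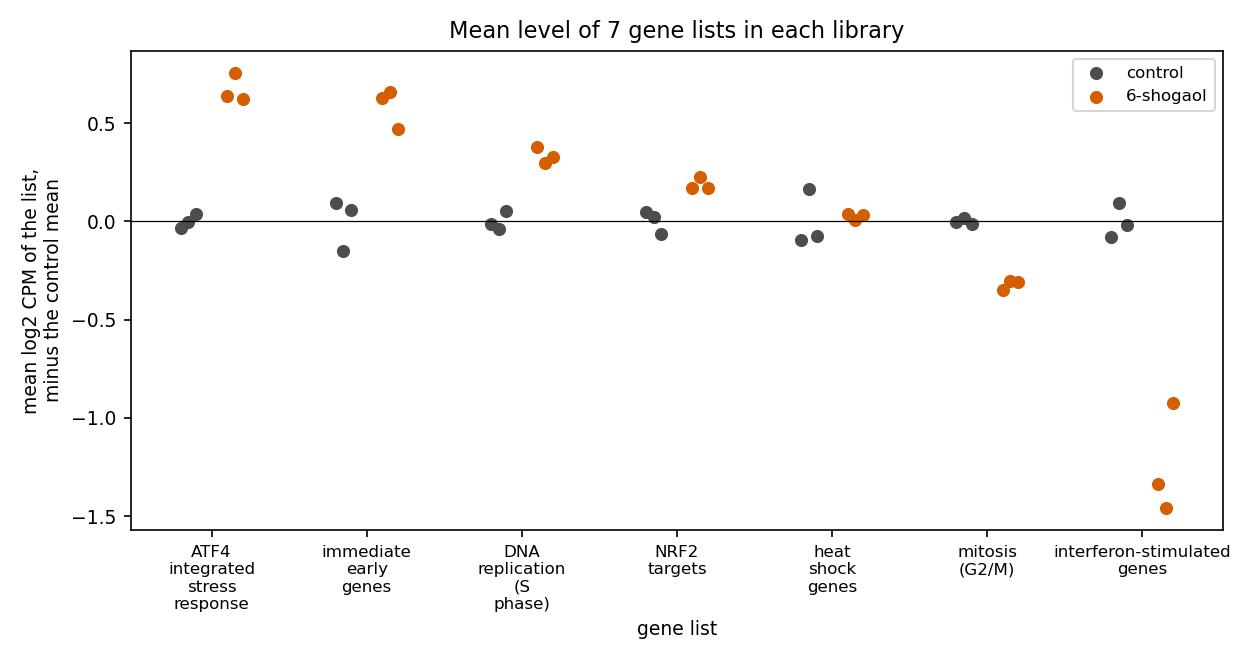
Mean log2 CPM of the tested members of 7 gene lists in each library, minus the control mean (vertical axis, log2 units); grey points are the 3 controls and orange points the 3 6-shogaol libraries. The treated libraries sit at -1.34, -1.46 and -0.93 for interferon-stimulated genes and at 0.64, 0.76 and 0.62 for ATF4 targets.

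Terms annotated in the deposited table were tested for enrichment among called genes. The hypergeometric test takes genes as independent, so with correlated members its p-values, here and below, may be too small. For the interferon-stimulated list the estimated inter-gene correlation was 0.50, and camera with that estimate did not call it (camera adjusted p = 0.091). Enrichment was not repeated on the calls of fits without 1 library or with the replicate block. Among the 302 lower genes with Gene Ontology terms, 24 belonged to the type I interferon signaling pathway, which held 49 of the 13544 background genes (1.09 anticipated by chance, hypergeometric adjusted p = 1.23e-23), and 1 called gene of that term was higher. Defense response to virus held 32 of them, out of 146 background genes (adjusted p = 8.69e-20), against 3 higher. The spindle term held 16, out of 202 (adjusted p = 0.00281), against 4 higher. Among the 304 higher genes 21 were annotated to DNA replication, which held 158 background genes (3.55 anticipated by chance, adjusted p = 1.89e-07), and 3 called genes of that term were lower. In all, 46 of the 3519 Gene Ontology terms tested passed among higher genes and 30 among lower genes. Among calls of at least 2-fold, DNA replication and spindle did not pass, while type I interferon signaling and defense response to virus did. Of 305 KEGG pathways 2 passed among higher genes, DNA replication (8 of 36 genes, adjusted p = 0.00188) and alanine, aspartate and glutamate metabolism (6 of 29 genes, adjusted p = 0.022), and 9 passed among lower genes, led by 2 viral infection pathways.

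Of the 26 lists, 9 were called higher and 9 lower with camera's preset correlation, 1 and 1 with an estimated correlation, immediate early and mitotic genes, and 10 and 7 by fry. The count of 651 called genes became 141, 98 and 170 without control replicates 1, 2 and 3, 1012, 166 and 174 without 6-shogaol replicates 1, 2 and 3, 378 with no filter on low counts and 1554 in DESeq2. Of the 42 named genes 20, 20 and 17 lost their call without control replicates 1, 2 and 3, and 3, 19 and 15 without 6-shogaol replicates 1, 2 and 3. With no filter on low counts 11 lost it, in limma on log2(FPKM + 1) with no filter 15, and with the replicate block 40.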

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

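The fits with robust moderation, with thinned counts and without mitochondrially encoded genes were chosen after the data were seen. No called direction of a named gene or list reversed in these alternatives, and RLE and upper-quartile scaling moved the median log2 fold change of all genes by less than 0.1. Against 322 higher and 329 lower genes, no filter gave 183 and 195 (32031 genes tested), DESeq2 764 and 790, and limma on log2(FPKM + 1) with no filter 159 and 118. DESeq2 called 641 of the 651 genes and gave the other 10 no adjusted p. Leaving out 1 library gave 44 to 480 higher and 54 to 532 lower genes, the highest without 6-shogaol replicate 1. Of genes changed at least 2-fold (45 higher, 60 lower), DESeq2 gave 80 and 109, limma on log2(FPKM + 1) 16 and 18, the same with no filter 14 and 15, limma on log2(FPKM + 0.1) 37 lower, and leaving out 1 library 23 to 56 higher and 31 to 87 lower. Same-numbered libraries deviated from their group means with correlations of -0.03, 0.06 and -0.04, so the numbers were not taken as pairs. With the replicate number as a block, edgeR called 3 genes higher and 0 lower (1645 and 1645 at unadjusted p under 0.05), and 3 and 0 at 2-fold, fewer degrees of freedom being left, while camera called 9 lists higher and 8 lower. Lists called higher and lower, 9 and 9, became 1 and 1 with an estimated correlation, and 8 to 9 and 7 to 8 without 1 library. Among calls of at least 2-fold, 2 Gene Ontology terms passed for higher and 11 for lower genes (46 and 30 with all calls), and 1 and 5 KEGG pathways (2 and 9). The mitochondrial share differed by -0.815 points, and by -0.192 without the 10 most abundant genes. Except where stated, the cause was not tested. Of 42 named genes, 19 passed in all 6 fits without 1 library, among them HSPA6, GDF15, TFRC, UNC5B, TRIB3, CHAC1, RRM2, CA9, NDRG1, IFIT1, OAS2, TACR1, CCNB1, KIF20A, MAVS, DNAJA1, HSPB1 and GFAP. Simulated 1.5-fold changes were recovered in 16% of genes, but only 50 genes were changed at each size, all above a minimum mean count. In the data 651 genes were called, some with smaller changes such as TPX2 (1.22-fold), so the share of such changes missed here was not measured.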

Other observations

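Chosen after the results were seen were the tests of depth and of a single library, the test of interferon transcripts, the test of HSPA6, and the genes named here outside the rule for named genes, SFPQ among them. Called genes included monocarboxylate transporters: 6 of 10 background genes annotated to monocarboxylic acid transport rose (hypergeometric adjusted p = 2.78e-05). Among them were SLC16A6 (log2 fold change 1.72), SLC16A7 (0.84) and SLC16A9 (0.71). Amino acid biosynthesis rose in 6 of 37 genes (adjusted p = 0.0213), with ASNS, the asparagine synthetase gene, at 1.01, PSAT1 of serine synthesis at 0.83 and ASS1, argininosuccinate synthase, at 0.64. Genes of cytokine activity were called higher in 10 of 91 (adjusted p = 0.00847), among them TNFSF18 (1.15), VEGFA (0.64) and SPP1 (0.72), while 3 genes of that term fell, CCL2 (-1.09) and TGFB2 (-0.40) among them. The phosphatases DUSP5 (1.08), DUSP6 (0.95), DUSP1 (0.55) and DUSP4 (0.42), which switch off MAP kinases, were the 4 higher genes of 11 in their term (adjusted p = 0.0134). This rests on few genes. DUSP6, DUSP1 and DUSP4 had edgeR adjusted p of 0.0345, 0.0438 and 0.0492, and DUSP5 lost its call in 4 of the 6 fits without 1 library.

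Lower genes were enriched for antigen presentation by MHC class I. Of 25 background genes in that term 5 fell (adjusted p = 0.0288), among them TAP1 (log2 fold change -0.84), TAP2 (-0.43) and TAPBP (-0.40), which load peptides. In the same term CANX (0.42) and SEC24D (0.34) rose. HSPA7, a neighbour and near copy of HSPA6, had 101, 65 and 55 counts with 6-shogaol and 0, 1 and 9 in controls. MT-ATP6 stood at 5099 CPM in 6-shogaol replicate 1 and between 1570 and 1708 CPM in the other 5 libraries.

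The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixed treated and control libraries, so a real group difference would widen its spread and hold down its calls. In 1 of the 10 splits, the real one, 651 genes were called, and the highest other split called 4. For changes of at least 2-fold, 1 of the 10 splits reached 105 genes, and the highest other reached 4. For lists, 1 of the 10 reached 18 called, and the highest other reached 9.

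Interferon-stimulated genes were lower, with a median log2 fold change of -1.18. Several technical explanations are argued against: the median was -1.21 after a trend on GC content and transcript length was removed over all genes, -1.12 in the 14 members without exon overlap, and at most -1.16 with any 1 library left out. After every library was thinned to the smallest total, 18 members were called lower. Totals ran only from 43516840 to 60018999 counts, too close for thinning to test unequal depth, so no conclusion on depth is drawn. Less interferon transcript in treated cells cannot be told apart from other routes, since the summed counts of type I and III interferon genes were too low, with 31, 20 and 42 in controls and 35, 36 and 43 with 6-shogaol. The list was fixed before the data were examined. That exposure to 6-shogaol may lower these genes stays a hypothesis tested only on these 6 libraries. MAVS, named by its adjusted p and not through this list, was also lower.

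The S-phase list exceeded the mitosis list by 0.65 in median log2 fold change. A bias of GC content or length and a single library are argued against, with a difference of 0.65 after the trend was removed and of at least 0.60 with any 1 library left out. The difference was 0.65 after thinning, but the library totals were too close for thinning to test unequal depth. A shift in the share of cells per phase and a change of transcription within phases were not tested, and either may underlie the difference.

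HSPA6 rose while the other heat shock genes did not rise as a group. Reads shared with the HSPA1A and HSPA1B pair are argued against: HSPA6 counts were 0.207%, 0.264% and 0.275% of that pair's counts in controls and 16.9%, 16.2% and 15.1% with 6-shogaol, the lowest treated share being 55.1 times the highest control share. Whether HSPA6 may outlast other transcripts of a heat shock response was not tested at this single time of 24 h.

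SFPQ, a splicing factor that other work has linked to transcription of genes with long introns, fell from 397 ± 8.35 to 218 ± 5.68 CPM (log2 fold change -0.86, edgeR adjusted p = 0.00209). The hypothesis that long genes fell with it was tested and found no such trend. Across genes, which are not independent replicates, Spearman's rho between genomic span and log2 fold change was 0.0922, and the 3011 genes over 100 kb had a median of 0.04 against -0.01 in the others.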
